A study of Rattus norvegicus with 20 samples.

How the data were processed

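MicroRNA (miRNA) levels were measured in the kidneys of male Wistar rats that weighed 80 to 100 g. Rats received aristolochic acid I (AAI, a nephrotoxic and genotoxic plant acid) at 40 mg per kg by intraperitoneal injection, and kidneys were collected on day 2, 4 or 6. The control rats received the vehicle, a mixture of polyethylene glycol and water, and were collected on day 6 only. Each of the 4 groups held 5 kidneys, and each kidney RNA was labelled with Cy3 and hybridized to 1 array, giving 20 arrays. Per the labels, RNA was extracted with a mirVana kit and labelled with an Agilent miRNA kit.

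Per the file headers, spots were read with Agilent Feature Extraction 10.7.1.1, and the deposited spot values are fluorescence intensity in arbitrary units, after background subtraction and before any scaling between arrays. The deposited flags that mark a miRNA as detected or a spot as an outlier are of the other kind, 0 or 1. The deposited series table holds log2 values for 740 entries. On it all undetected miRNAs of an array share 1 value. Arrays share their highest value (17.39) and have nearly equal means (0.4183 to 0.4187), but their medians ranged from -3.32 to -3.01. How that table was made is not stated, so it was used only as an alternative. All per-array columns of that table were matched to their sample. Per the file headers, probe coordinates refer to the rn4 rat genome build.

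The arrays carried 719 rat miRNAs on 1730 probes and 14380 spots, with 5 to 20 spots per probe. No spot was saturated (0 over all arrays), and 373 to 559 spots per array, control spots included, carried an outlier flag. Flagged spots were left out, except where all spots of a probe were flagged. The signal of a miRNA was the sum over its probes of the mean background-subtracted spot intensity. It was divided by the 75th percentile of the array, taken over the 231 miRNAs detected on all 20 arrays because at most 45.6% of miRNAs were detected on any array. A floor of 0.00640 was then set and log2 taken, so that 1 unit is a doubling relative to that percentile. Of 5240 tested values, 12 lay at the floor. A miRNA was tested if it was detected on all 5 arrays of at least 1 group, which left 262 of the 357 that were detected on at least 1 array. The number of arrays limits the precision of each value.

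Group means were fitted with limma 3.58.1 in R 4.3.3 (files were read with data.table, version 1.17.8), with 16 residual degrees of freedom and 2.17 from the prior. The 6 pairwise contrasts were tested two-sided with moderated statistics, and Benjamini-Hochberg adjustment was applied over the 262 miRNAs within each contrast. A miRNA was called at an adjusted p under 0.05, and intervals of a fold change are at 95%. An F test over the 4 groups used the same fit. Errors given after ± with a fold change are standard errors, and those with a level are standard deviations over 5 arrays. Comparisons of array-level measures used two-sided exact permutation tests over 252 splits.

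The comparisons, the alternatives, the rule for named miRNAs and 14 lists of miRNAs were fixed before the data were examined. The lists were p53-induced, kidney-enriched, miR-200 family, reported higher in injured kidney, miR-17 cluster and paralogs, let-7 family, miR-29 family, miR-322 cluster and Dlk1-Dio3 imprinted cluster miRNAs, and 5 lists for other cell types or tissues (leukocyte, erythrocyte, stromal and smooth muscle, endothelial, and miRNAs of liver, muscle, brain and pancreas). The 11 lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, again with the estimated correlation, and with fry, all from limma. Members were counted with the adjustment over all tested miRNAs and adjusted over the list alone. The rule named, for each AAI day against vehicle, the 10 largest called changes per direction among miRNAs detected on all 5 arrays of both groups. It added up to 5 per direction that were detected on all 5 arrays of one group and none of the other. Between AAI days it named the 5 largest per direction, and every tested list member could be named.

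The arrays sat on 3 slides, each scanned as 1 run. Slide 3 held 4 vehicle arrays, and slide 2 held 1 vehicle array, all 5 AAI day 2 arrays and 2 AAI day 4 arrays. Slide 1 held 3 AAI day 4 arrays and all 5 AAI day 6 arrays. Slide was therefore fitted as a fixed block, as a random block (consensus correlation 0.329) and by comparison within slides that held both groups. The other alternatives were normexp background correction with an offset of 50, quantile normalization, other percentiles or medians for scaling, no scaling, other summaries of probes, other detection filters, a floor 2 times as high, replicate number as a block, a trended and robust variance model, the deposited series table, a fit to only the 2 groups compared, and leaving out each array in turn. Scaling to labelling spike-ins and a pair of settings that left out AAI day 4 array 2 were added after seeing the data.

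The steps were tested on simulated data, 10 sets with 20 miRNAs changed at each of 1.5-, 2- and 4-fold in AAI day 6 among the 262 tested. For AAI day 6 against vehicle, 63.5%, 88.5% and 98.5% of these were recovered, with a median of 7 false calls per set (range 1 to 143). Of all 220 false calls 215 were lower, although raised and lowered miRNAs were simulated in equal number. In the set with 143, all lower, percentile scaling shifted unchanged miRNAs by -0.47 on the log2 scale. With scaling to the median of detected miRNAs, false calls had a median of 1 (range 0 to 5). With slide as a fixed block, recovery at these sizes was 19.5%, 44.5% and 82%, and false calls had a median of 1 (range 0 to 34), of which 40 of 46 were lower, with all 34 of the highest set. For AAI day 4 against vehicle, a let-7 list of 8 members lowered 1.5-fold was called in 10 of 10 sets. The simulated miRNAs varied independently of one another and without a slide effect. These rates therefore do not cover list members that vary together or slides that differ. No pair of arrays was identical (0 of 190). Plasma, which the series title mentions, was not analysed here.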

Results

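The 20 arrays measured miRNA levels in kidneys of rats given vehicle or AAI, with 5 kidneys at each of AAI day 2, day 4 and day 6 and 5 vehicle kidneys at day 6. The number of detected miRNAs per array ranged from 250 to 328. Its mean was 264.6 ± 4.16 (SD, n = 5) in vehicle, 269.4 ± 11.5 at day 2, 287 ± 23.5 at day 4 and 289.2 ± 23.1 at day 6. The 75th percentile signal averaged 367 ± 51.9 in vehicle and 452 ± 83.6, 472 ± 73.8 and 480 ± 96.3 at day 2, 4 and 6, ratios of 1.23, 1.29 and 1.31. In exact permutation tests the adjusted p of these 6 comparisons was 0.0833 or higher. AAI day 4 array 2 had the 328 detected miRNAs, against 269 to 284 on the other arrays of its group. Between arrays of a group the correlation of levels across miRNAs, which are not independent replicates, was 0.912 to 0.996.

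The comparison of AAI day 6 with vehicle asked which kidney miRNAs differed after 6 days at the same collection time. The p53-responsive miR-34a-5p (rn4 chromosome 5, 167187918 to 167187937) rose 7.57-fold (95% interval 4.40 to 13.0), from a log2 level of -2.52 ± 0.17 to 0.40 ± 0.79 (SD, n = 5 each). Its paralogs miR-34c-5p and miR-34b-5p, which share a locus on chromosome 8 (starts 54422067 and 54422584), rose 2.43-fold (1.61 to 3.65) and 2.15-fold (1.44 to 3.21). The injury-associated miR-21-5p (chromosome 10, 74864519 to 74864538) rose 2.16-fold (1.52 to 3.09). The red-cell miRNA miR-451-5p (chromosome 10, 64129535 to 64129555) fell 6.62-fold (4.06 to 10.8), from -0.37 ± 0.65 to -3.10 ± 0.66. All 5 AAI arrays lay beyond all 5 vehicle arrays for each of these 5 miRNAs, as the plot of levels on each array shows.

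**Figure D1:**
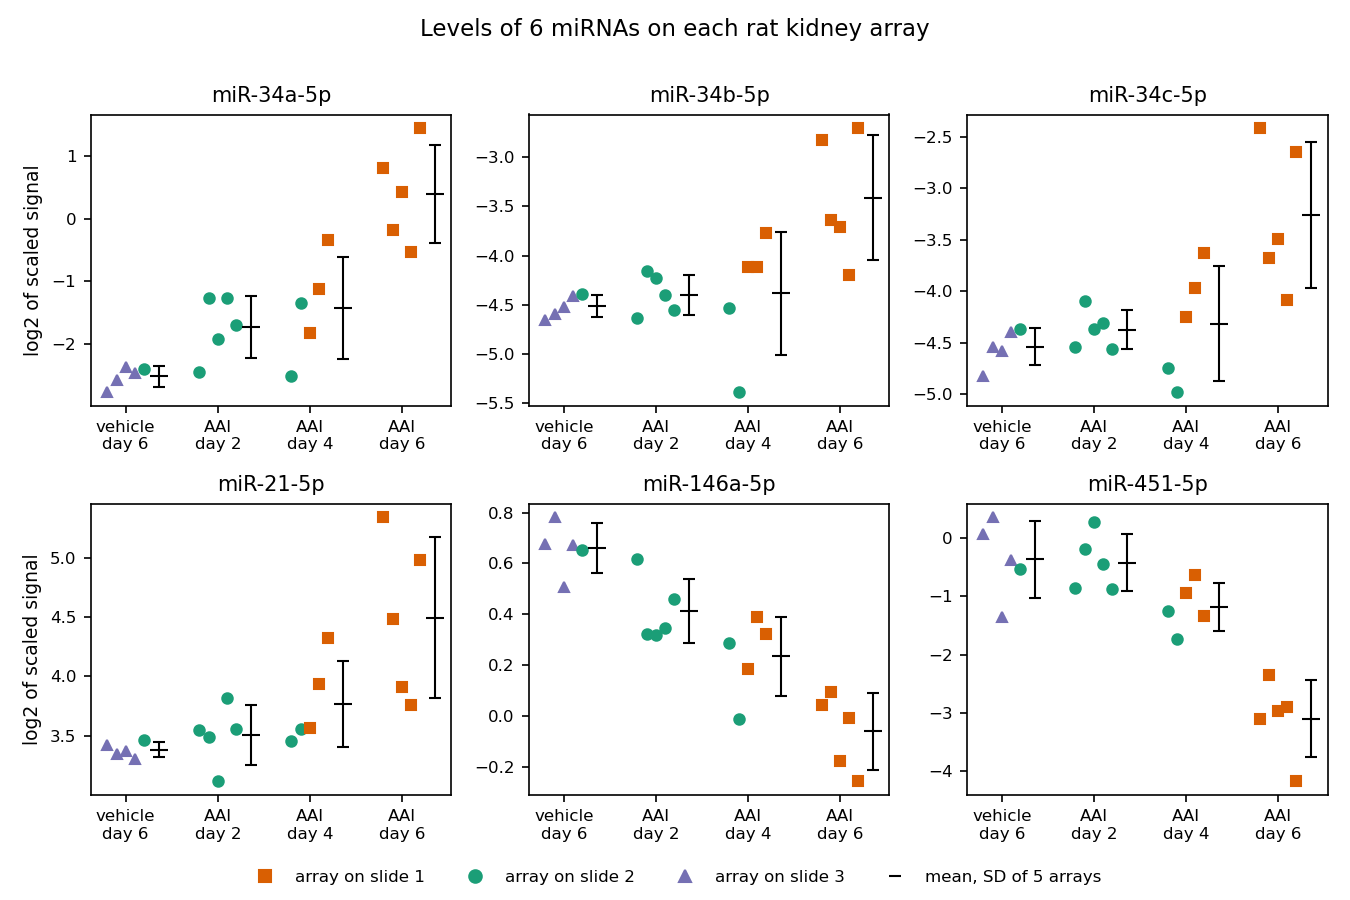
Log2 of the scaled signal (vertical axis) of 6 miRNAs on each array by group (horizontal axis), with marker shape and colour for the slide and a bar for the mean and SD of 5 arrays. At day 6 the mean of miR-34a-5p was 0.40 against -2.52 in vehicle and that of miR-451-5p was -3.10 against -0.37. All 5 day 6 arrays sit on slide 1 and 4 of the vehicle arrays on slide 3, and with slide as a fixed block the day 6 difference of miR-34c-5p was 0.19 and of miR-34b-5p 0.02.

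In limma, 68 of 262 miRNAs passed the threshold at day 6, 19 higher and 49 lower, of which 12 and 1 changed at least 2-fold (108 at an unadjusted p under 0.05). Groups did not overlap for 61 miRNAs (23.3%), where chance gives 0.794%. The adjusted p was 1.60e-05 for miR-34a-5p and miR-451-5p, 0.00285 for miR-34c-5p and miR-21-5p, and 0.00656 for miR-34b-5p. Also higher were miR-6216 (log2 change 1.56 ± 0.34) and miR-341 (1.35 ± 0.22). miR-23a-5p (2.86 ± 0.35) was higher and detected on 5 of 5 AAI arrays and 0 of 5 vehicle arrays. Its fold was 6.99 over vehicle values raised to the lowest detected signal of the array. That fold leaves out its error, so it is an estimate and not a lower limit. The opposite strand miR-21-3p, detected on 3 of 5 vehicle arrays and so chosen after its values were seen, was 7.01-fold higher. Past the threshold but dependent on single arrays were miR-3473 (1.70 ± 0.53) and miR-3584-5p (1.57 ± 0.53). They lost the call without vehicle array 1 (adjusted p 0.0702 and 0.0722) or 5 (0.0658 and 0.0859), or AAI day 6 array 3 (0.0731 and 0.105) or 4 (0.0645 and 0.0931), and miR-3584-5p also without vehicle array 3 (0.0576). Besides miR-451-5p, the largest falls were in miR-192-3p of the tubular miR-192 locus (-0.81 ± 0.15), miR-146a-5p (-0.72 ± 0.09), miR-185-5p (-0.69 ± 0.11), miR-203b-3p (-0.66 ± 0.13) and miR-342-3p (-0.65 ± 0.12).

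The lower calls at day 6 depended on how arrays were scaled, and the higher calls kept their sign under each scaling. Median log2 changes of the tested miRNAs were -0.11 with percentile scaling, 0.26 unscaled and 0.14 with spike-in scaling. Higher and lower calls numbered 33 and 1 unscaled, 21 and 2 with spike-in scaling, and 16 and 11 with scaling to the median of detected miRNAs. All 19 higher calls were positive unscaled, but only 22 of the 49 lower calls were negative. With spike-in scaling 43 of the 49 were negative, and all 49 were with scaling to the median of detected miRNAs, to the 75th percentile over all miRNAs and with quantile normalization. miR-451-5p stayed at -2.36 unscaled and past the threshold, whereas miR-146a-5p, at -0.35, did not (adjusted p = 0.127, range over its alternatives 1.25e-05 to 0.127). The software's own total signal, which made 23 calls (19 higher and 4 lower), turned miR-34c-5p to -0.94 and miR-34b-5p to -0.90, and its ratio to the probe sum for miR-34b-5p ranged from 0.657 to 11.3 between arrays.

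Slide overlapped with group, since no slide held both vehicle and AAI day 6 arrays. With slide as a fixed block, 90 miRNAs passed, 30 higher and 60 lower, of which 45 were called without it, and with slide as a random block 60 passed. Of the 21 miRNAs the rule named at day 6, all 21 kept their sign under the fixed block and 12 stayed past the threshold. Among those that lost the call in limma were miR-192-3p (adjusted p = 0.0874), miR-203b-3p (0.0781) and miR-341 (0.0953). miR-451-5p was -3.07 ± 0.78 (adjusted p = 0.0131, range 1.14e-05 to 0.0658), miR-146a-5p -0.87 ± 0.20 (0.0123) and miR-34a-5p 1.96 ± 0.83 (0.0761, range 1.64e-05 to 0.310). miR-21-5p was 0.60 ± 0.56 (0.422, range 6.17e-04 to 0.627), miR-34c-5p 0.19 ± 0.56 (0.795, range 6.91e-04 to 0.828) and miR-34b-5p 0.02 ± 0.54 (0.975, range 0.00196 to 0.975). These values rest on vehicle array 5 and AAI day 4 arrays 1 and 2, which link the slides, and without AAI day 4 array 2 the fixed block left 0 of 262 past the threshold in limma, with miR-34a-5p at 1.37 ± 0.89 and miR-451-5p at -2.83 ± 0.88. Within AAI day 4, the 2 arrays on slide 2 differed from the 3 on slide 1 in 61 of 262 miRNAs, and in 0 by limma without array 2 (17 at an unadjusted p under 0.05). That last comparison has 1 array against 3, with the spread pooled over all groups, so it does not show that slide had no effect.

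All 6 tested members of the p53-induced list passed at day 6, in opposite directions. The 3 miR-34 members rose, while miR-194-5p (-0.63 ± 0.13), miR-192-5p (-0.56 ± 0.13) and miR-107-3p (-0.33 ± 0.08) fell, with the same 3 and 3 adjusted over the list alone. Unscaled, miR-107-3p reversed to 0.04, and miR-192-5p and miR-194-5p were -0.19 and -0.26. The list did not shift as a whole (mean 0.63, camera adjusted p = 0.373, or 0.642 with an estimated correlation), but its members changed in either direction (fry mixed adjusted p = 0.0210). With slide as a fixed block the mean was -0.04 (camera 0.805).

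Of 14 tested kidney-enriched miRNAs, 6 fell and 8 did not pass, and the count was 6 adjusted over the list alone. They included the tubular miR-192-5p and miR-194-5p and miR-204-5p (-0.42 ± 0.10), abundant in renal epithelium. The other 3, miR-196a-5p, miR-196b-5p and miR-30e-3p, fell less and were positive unscaled (0.0550, 0.0396 and 0.0559). Leaving out the scaling moved all day 6 changes up together, their median from -0.11 to 0.26. That move takes up most of the fall of miR-204-5p as well. The mean of all 14 was -0.25 (camera adjusted p = 0.102, or 0.642 with an estimated correlation; fry 0.0413), -0.55 with slide as a fixed block (camera 0.00929, or 0.904 with an estimated correlation; range over settings 0.00929 to 0.250), and 0.12 unscaled. Beside them the leukocyte list had a mean of -0.47 over 6 members, 2 of which fell, miR-146a-5p and miR-342-3p (3 adjusted over the list alone; camera 0.105, or 0.642 with an estimated correlation; fry 0.00487). Its member miR-142-3p was -0.69 ± 0.27 (adjusted p = 0.0628) and the list mean was -0.72 with slide as a fixed block (camera 0.470). Unscaled it was -0.10, where the list passed (camera 0.0106, or 0.955 with an estimated correlation), as it did with spike-in scaling (-0.22, camera 0.0221, or 0.909 with an estimated correlation; range over settings 0.0106 to 0.680). In the stromal and smooth-muscle list 1 of 5 fell (mean -0.17, camera 0.373, or 0.642 with an estimated correlation; 0.20 unscaled, -0.46 in the fixed block). This was miR-214-3p (-0.25 ± 0.08), whose call was lost without vehicle array 2, 4 or 5 or AAI day 6 array 2, 4 or 5 (adjusted p 0.0564 to 0.0862) and which was 0.12 unscaled. Of 2 endothelial members 0 passed in limma (mean -0.17, and 0.20 unscaled; 1 lower adjusted over the list alone), with miR-126a-3p at -0.21 (adjusted p = 0.0502). The only tested member of the erythrocyte list was miR-451-5p. Of 2 tested miRNAs of other tissues, miR-133b-3p and miR-375-3p, 0 passed (mean -0.18).

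Among 11 tested miRNAs reported higher in injured kidney, 3 rose and 2 fell (5 and 2 adjusted over the list alone). miR-34a-5p, miR-21-5p and miR-18a-5p (0.71 ± 0.25) rose, and miR-146a-5p and miR-214-3p fell. The values of miR-146b-5p, a regulator of inflammatory signalling, and miR-132-3p, detected on only 2 of 5 vehicle arrays, were 0.80 ± 0.33 (adjusted p = 0.0762) and 0.72 ± 0.30 (0.0828). The list mean was 0.44 and its median 0.07 (camera 0.171, or 0.642 with an estimated correlation; fry mixed 3.43e-05), and with slide as a fixed block the mean was -0.03 (camera 0.947). The call of miR-18a-5p was lost without vehicle array 1, 3, 4 or 5 or AAI day 6 array 1, 2 or 5 (adjusted p 0.0624 to 0.105), and it reversed to -0.30 in the fixed block. miR-214-3p lost its call without vehicle array 2, 4 or 5 or AAI day 6 array 2, 4 or 5 (0.0564 to 0.0862), and was 0.12 unscaled.

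**Figure D2:**
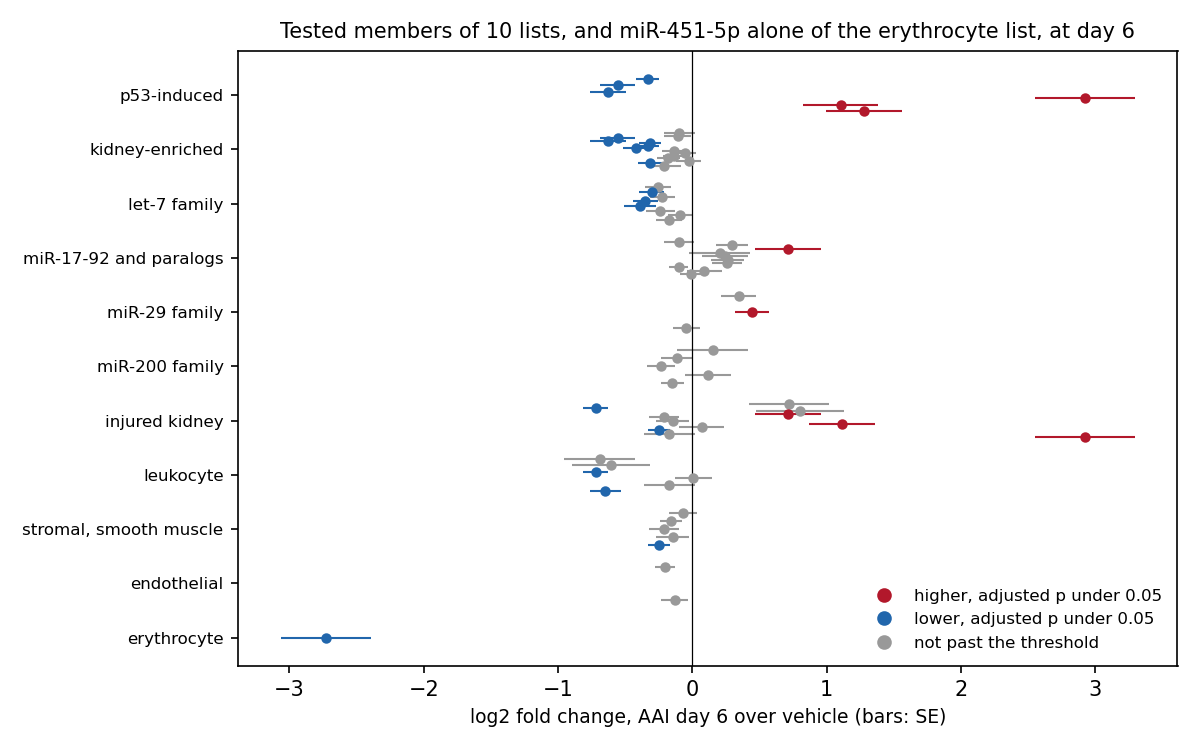
Log2 fold change of AAI day 6 over vehicle (horizontal axis, bars for the SE) of each tested member of 10 of the 14 fixed lists and of miR-451-5p, the only tested member of the erythrocyte list (vertical axis), coloured by whether it passed the adjusted threshold. The 3 p53-induced members miR-34a-5p, miR-34c-5p and miR-34b-5p lie to the right and miR-451-5p lies farthest to the left. Unscaled, the mean of the kidney-enriched and let-7 lists was 0.12, against -0.25 here.

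Of 8 let-7 family members, which repress growth-promoting transcripts, 3 fell at day 6 (let-7b, let-7d and let-7e; 5 adjusted over the list alone). Their mean was -0.25 (camera 0.102, or 0.642 with an estimated correlation; fry 0.0484), -0.71 with slide as a fixed block (camera 0.00226, or 0.904 with an estimated correlation; range over settings 5.36e-04 to 0.447), and 0.12 unscaled. let-7b lost its call without vehicle array 3 (adjusted p = 0.0525) or AAI day 6 array 3 (0.0503), and let-7e without vehicle array 3 (0.0524) or AAI day 6 array 3 (0.0599) or 4 (0.0577). In the miR-29 family, which targets matrix genes, miR-29b-3p rose (0.44 ± 0.13) and 2 of 3 members passed adjusted over the list alone (mean 0.25, camera 0.132, or 0.642 with an estimated correlation). In the fixed block the mean was 0.02. Of 10 members of the growth-associated miR-17 cluster and paralogs, miR-18a-5p rose, but 0 passed adjusted over the list alone (mean 0.19, camera 0.102, or 0.642 with an estimated correlation; -0.33 in the fixed block). Without vehicle array 1, 3, 4 or 5 or AAI day 6 array 1, 2 or 5, the call of miR-18a-5p was lost (0.0624 to 0.105). In limma 0 of 5 miR-200 family members passed (mean -0.05, camera 0.950), 0 of 6 of the miR-322 cluster (0.13, camera 0.170) and 0 of 4 tested members of the Dlk1-Dio3 list (-0.05, camera 0.841), with estimated-correlation p of 0.976, 0.642 and 0.842. That list does not cover its whole region. miR-341, called higher above (1.35 ± 0.22), was not on it but lies near the listed miR-300-3p (chromosome 6, starts 134203581 and 134405292). By camera 0 of 11 lists passed at day 6, 1 without AAI day 6 array 2 and 2 without array 4.

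At day 4 against vehicle, which asked what differed before day 6, miR-23a-5p was higher (2.66 ± 0.35), detected on all 5 AAI and 0 of 5 vehicle arrays. Its fold of 6.08 over vehicle values raised to the lowest detected signal is again an estimate, not a lower limit. miR-21-3p rose by 2.06 ± 0.32 log2 units (adjusted p = 5.88e-04) and miR-341, of an imprinted locus, rose 2.63-fold (1.90 to 3.64). With normexp background correction none of the day 4 calls was kept. miR-146a-5p, a brake on inflammatory signalling, fell (-0.42 ± 0.09, adjusted p = 0.00786, range over its alternatives 0.00641 to 0.700). Its call was lost in 10 of 31 alternatives, among them no scaling (-0.06, 0.700), spike-in scaling (-0.24, 0.573), slide as a fixed block (-0.51, 0.0697) or random block (-0.45, 0.0594) and within slide 2 (-0.49, 0.261). The calls of miR-341 and miR-21-3p were lost with slide as a fixed block (0.104 and 0.0808) and within slide 2 (0.331 and 0.145), with ranges of 1.70e-05 to 0.649 and 1.45e-05 to 0.859. miR-34a-5p was 1.09 ± 0.37 (adjusted p = 0.110), miR-451-5p -0.81 ± 0.34 (0.157) and miR-21-5p 0.39 ± 0.24 (0.339).

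In limma 9 miRNAs passed at day 4, 6 higher and 3 lower (58 at an unadjusted p under 0.05), and groups did not overlap for 18 miRNAs (6.87%, chance 0.794%). The others were miR-489-3p (0.63 ± 0.13), miR-465-5p (1.61 ± 0.34) and miR-551b-5p (1.22 ± 0.27), higher, and miR-196c-5p (-0.35 ± 0.08) and miR-361-5p (-0.29 ± 0.07), lower. miR-21-3p, miR-465-5p and miR-551b-5p were chosen after their values were seen. The call of miR-196c-5p was lost without vehicle array 1 (adjusted p = 0.0687) or AAI day 4 array 1 (0.0533). That of miR-361-5p was lost without any vehicle array or AAI day 4 array 1, 3 or 5 (0.0511 to 0.0769). Without AAI day 4 array 4 the count was 14. Unscaled, where the median change of all tested miRNAs was 0.29 (0.11 with spike-in scaling), 14 were higher and 0 lower, miR-196c-5p was 0.02 and miR-361-5p 0.07. With spike-in scaling 9 were higher and 0 lower, and with scaling to the median of detected miRNAs 7 and 0. With slide as a fixed block 19 passed, 4 of them among the 9, within slide 2 (2 AAI arrays and 1 vehicle array, assumed to vary like the AAI arrays) 8 passed with 0 shared, and with slide as a random block 3 passed. All 9 kept their sign in these settings, and under the fixed block without AAI day 4 array 2 limma called 0.

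The let-7 family at day 4 had 0 of 8 members past the threshold in limma, and 5 lower adjusted over the list alone. All 8 values were negative (mean -0.22, camera adjusted p = 0.0294, or 0.921 with an estimated correlation), but unscaled all 8 were positive (mean 0.14). The mean was -0.52 with slide as a fixed block (camera 3.65e-04, or 0.842 with an estimated correlation; range over settings 3.08e-05 to 0.619) and -0.49 within slide 2 (camera 0.00431, or 0.763 with an estimated correlation), a value that rests on 1 vehicle array, assumed to vary like the AAI arrays. Without vehicle array 3 or 5 or AAI day 4 array 1, camera called 0 lists, and fry called 0 with all arrays. Of the leukocyte list, miR-146a-5p was the 1 of 6 that fell (mean -0.31, camera 0.207; 0.05 unscaled, -0.44 in the fixed block). Among injured-kidney miRNAs 1 of 11, again miR-146a-5p, fell. In the p53-induced list 0 of 6 and in the kidney-enriched list 0 of 14 passed in limma.

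At day 2 against vehicle, 4 miRNAs passed in limma, all higher (29 at an unadjusted p under 0.05). These were miR-21-3p (3.22-fold, interval 2.02 to 5.15), miR-465-5p (1.53 ± 0.34), miR-551b-5p (1.22 ± 0.27) and miR-23a-5p, detected on 4 of 5 AAI and 0 of 5 vehicle arrays and so given without a fold. None was detected on all 5 arrays of both groups, so they were chosen after their values were seen. The first 3 were detected on 3, 1 and 2 of 5 vehicle arrays, so their folds rest in part on vehicle values under detection. miR-34a-5p was 0.80 ± 0.37 (adjusted p = 0.427) and miR-451-5p -0.05 ± 0.34. Groups did not overlap for 11 miRNAs (4.20%, chance 0.794%). Within slide 2, where the 1 vehicle array was assumed to vary like the AAI arrays, and with slide as a fixed or random block, 0 passed, with all 4 keeping their sign. miR-21-3p was 1.67 ± 0.53 within slide 2 (adjusted p = 0.575), 1.66 ± 0.58 in the fixed block (0.977) and 1.72 ± 0.43 in the random block (0.0835), with a range over its alternatives of 2.47e-04 to 0.977. miR-465-5p lost its call without vehicle array 3 (0.0668) or 4 (0.0553) or AAI day 2 array 4 (0.0714) or 5 (0.0547), and miR-551b-5p without vehicle array 1 (0.0591) or 5 (0.0677) or AAI day 2 array 4 (0.0714), which alone left 2 calls. With normexp background correction 0 passed and the 4 values were near 0 and negative (miR-23a-5p -0.11). Unscaled, 9 passed, and the median of all tested miRNAs was 0.25 (0.21 with spike-in scaling). No list shifted (0 of 11 by camera), but without AAI day 2 array 3 there was 1. Of the Dlk1-Dio3 list, miR-382-5p alone passed adjusted over the list alone (0.75 ± 0.22, adjusted p = 0.0129), but not over all tested miRNAs. It was detected on 3 of 5 vehicle arrays and on all 5 arrays only at day 2, the group through which it was tested. Its change therefore also rests in part on vehicle values under detection.

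The AAI days were compared with one another to ask when levels changed. From day 4 to day 6 miR-34a-5p rose 3.55-fold (2.07 to 6.11, adjusted p = 0.0145) and miR-451-5p fell 3.77-fold (-1.91 ± 0.34, 0.00538), the 2 calls by limma (24 at an unadjusted p under 0.05). Within slide 1, which held 3 day 4 and all day 6 arrays, miR-451-5p was -2.05 ± 0.35 (0.0474, range 0.00222 to 0.0919) and miR-34a-5p 1.56 ± 0.51 (0.233, range 0.00414 to 0.255). With slide as a fixed block they were -2.12 ± 0.40 (0.0174) and 1.49 ± 0.42 (0.106). Without AAI day 4 array 1 or 3, or AAI day 6 array 1 or 5, the call of miR-34a-5p was lost (adjusted p 0.0529, 0.0596, 0.0601 and 0.0534), leaving 1. The count was 6 without AAI day 4 array 2, 5 without array 5, and 8 without AAI day 6 array 4. Injured-kidney miRNAs were higher by camera at the preset correlation only (mean 0.39, camera 0.00931, or 0.637 with an estimated correlation), and by fry 0 lists passed. Of these 11 miRNAs 1 passed the threshold, and 2 higher and 1 lower passed adjusted over the list alone. Within slide 1 their mean was 0.29 (camera 0.742, range over settings 9.37e-04 to 0.742) and in the fixed block 0.22 (0.361).

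From day 2 to day 6, 29 miRNAs passed, 9 higher and 20 lower. miR-34a-5p was 2.12 ± 0.37 higher on the log2 scale (adjusted p = 0.00263), and miR-451-5p (-2.67 ± 0.34, 6.55e-05), miR-146a-5p (-0.47 ± 0.09, 0.00480) and the metabolic miR-378b (-0.45 ± 0.09, 0.00592) were lower. miR-34c-5p (1.11 ± 0.28) and miR-21-5p (0.99 ± 0.24) were also higher, and lost the call without AAI day 2 array 5 (both 0.0505) or AAI day 6 array 5 (both 0.0592). miR-6216 (1.28) lost it without AAI day 2 array 5 (0.0505) or AAI day 6 array 1 (0.0619) or 3 (0.0584). The miR-29 family, with miR-29a-3p (0.43) and miR-29b-3p (0.47) past the threshold, was higher by camera at the preset correlation only (mean 0.34, camera 0.0226, or 0.606 with an estimated correlation). In the fixed block its mean was 0.19 (camera 0.322, range over settings 0.00197 to 0.322), and by fry 0 lists passed from day 2 to day 6. Without AAI day 2 array 2 or 5 or AAI day 6 array 5, miR-29b-3p lost its call (0.0562, 0.0505 and 0.0653). miR-29a-3p kept it only without AAI day 6 array 4 and lost it without each of the other arrays (0.0513 to 0.110). The count of 29 was 15 without AAI day 2 array 1 or 2, 6 without array 5, and 19, 16 and 8 without AAI day 6 array 1, 3 and 5. No slide held both groups, and in the fixed block 95 passed (28 higher, 67 lower; 17 of the 29), with all 10 named miRNAs keeping their sign and 3 past the threshold, miR-6216, miR-451-5p and miR-146a-5p. Without AAI day 4 array 2 the fixed block left 0 in limma. Calls were 2 higher and 1 lower unscaled, 1 and 1 with spike-in scaling, and 3 and 2 with scaling to the median of detected miRNAs.

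Between day 2 and day 4, 0 miRNAs passed in limma (20 at an unadjusted p under 0.05), and 34 passed with slide as a fixed block. By camera at the preset correlation 2 of 11 lists passed, and 0 with the estimated correlation or by fry. The 2 were the let-7 family, lower (mean -0.15, camera 0.00938, or 0.842 with an estimated correlation), and the miR-29 family, higher (mean 0.24, camera 0.00436, or 0.428 with an estimated correlation). Of either family 0 members passed the threshold. Within slide 2 the means were -0.36 (camera 0.00754, or 0.601 with an estimated correlation; range over settings 1.26e-04 to 0.399) and 0.17 (0.162, range 3.09e-04 to 0.225), and in the fixed block -0.38 (7.84e-04, or 0.669 with an estimated correlation) and 0.15 (0.225). The F test over the 4 groups called 47 of 262 (76 at an unadjusted p under 0.05), 31 without vehicle array 1 or 5 or AAI day 6 array 3, and 71 without AAI day 4 array 2.

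The days shared their calls in part. miR-23a-5p, miR-21-3p, miR-465-5p and miR-551b-5p were higher at all 3 days. None of them was detected on every vehicle array, and with normexp background correction none was called at day 2 or day 4. At day 2 they were near 0 and negative with that correction. Day 4 and day 6 shared 6 higher calls (0.435 expected if independent) and 3 lower (0.561), day 2 and day 4 shared 4 higher (0.0916) and day 2 and day 6 shared 4 higher (0.290). Across miRNAs, which are not independent, the fold changes of day 2 and 4, 2 and 6, and 4 and 6 correlated at 0.783, 0.713 and 0.890, where 100 simulations of unchanged groups sharing 5 controls gave means of 0.459, 0.439 and 0.470. Each value lay within its simulated range (-0.557 to 0.965, -0.545 to 0.942 and -0.511 to 0.989), as sharing 5 controls can give. With the controls split so that no vehicle array served both days, mean correlations over 20 splits were 0.609, 0.584 and 0.774 (lowest 0.243, 0.231 and 0.562), to which shared vehicle arrays do not contribute. A slide effect can still contribute, because slide 3 held 4 vehicle arrays and no AAI array, so it enters the changes of both days. Unchanged groups split in the same way gave means of 0.0255, 0.00783 and 0.00607, and 9, 5 and 0 of 100 simulations reached the observed mean. Only that of day 4 and 6, which share slide 1, lay beyond all simulations. Covariances were 0.107, 0.134 and 0.213 against simulated means of 0.0333, 0.0273 and 0.0285, and only that of day 4 and 6 exceeded the highest simulated value (0.258, 0.175 and 0.153). Since these days share slide 1, a slide effect could also give that excess. Shared calls numbered 4, 4 and 9, against simulated means of 0.63, 0 and 0 (highest 63, 0 and 0), and means of 1.1, 1.25 and 3.9 with split controls. Unchanged groups have few calls to share, so the simulated counts do not show whether the days agree. The single vehicle group was collected at day 6, so the day 2 and day 4 comparisons also differ in collection time.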

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

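The tests of leukocytes and of a lower share of tubular epithelium were chosen after the results were seen, as were the values relative to all tested miRNAs, also on left-out arrays, the spike-in scaling and the settings without AAI day 4 array 2.

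Higher miRNAs at AAI day 6, led by miR-34a-5p, numbered 19 with a median log2 change of 1.28. With spike-in scaling their median was 1.53 ± 0.17, and other scalings gave 1.17 (75th percentile over all miRNAs) to 1.65 (unscaled). Spike-in scaling and no scaling raised the changes of all miRNAs together, so they could not test scaling as the whole cause. Slide as the whole cause is not excluded by 1.18 ± 0.29 with slide as a fixed block (1.02 ± 0.26 without AAI day 4 array 2). The 19 were chosen on these same arrays, and the errors leave out that choice. The block also rests on the few arrays that link the slides. Entry of leukocytes cannot be decided. The mean of 4 leukocyte miRNAs was -0.37 ± 0.17, and in none of these settings did it lie more than 2 errors above 0. In other settings it lay within 2 errors of 0 (0.00418 ± 0.219 unscaled, -0.64 ± 0.43 in the fixed block and -0.26 ± 0.43 there without AAI day 4 array 2). Its difference from the median of the higher miRNAs, which no factor per array moves, was -1.64 ± 0.25. In the fixed block that difference was -1.82 ± 0.51, and -1.28 ± 0.53 without that array. The higher miRNAs were chosen on these arrays for being high, so lists not chosen that way tend to fall below them. The difference therefore does not test leukocytes. Among single miRNAs, slide stays open for miR-34c-5p (0.19), miR-34b-5p (0.02), miR-21-5p (0.60 ± 0.56) and miR-18a-5p (reversed to -0.30) in the fixed block. It stays open for miR-34a-5p too, whose call ended there with a lower value and a wider error (2.92 ± 0.37 to 1.96 ± 0.83). Without AAI day 4 array 2 miR-34a-5p was 1.37 ± 0.89, within 2 errors of 0. Within slide 1 it was 1.56 ± 0.51 from day 4 to day 6 (limma adjusted p = 0.233). A difference between slides does not enter that value, but that slide holds no vehicle array. A response to AAI is a hypothesis found and tested on the same data.

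Lower miRNAs at day 6 numbered 49 with a median of -0.35, and scaling of the arrays could account for the fall itself, since their median was 0.0171 ± 0.151 unscaled (-0.10 with spike-in scaling), where the median of all tested miRNAs moved from -0.11 to 0.26 (0.14). It is argued against for their place below other miRNAs, which no factor per array moves: lower calls made without 1 vehicle and 1 AAI array had, less the median of all tested miRNAs, a median of -0.26 ± 0.04 on the left-out pair (mean of 25 pairs, all below 0). Slide as the whole cause is not excluded either. With slide as a fixed block the median was -0.63 ± 0.13, of which -0.32 was shared by the median of all tested miRNAs. That left -0.31 ± 0.08 (-0.39 ± 0.10 without AAI day 4 array 2), for miRNAs chosen on the same arrays. A lower share of tubular epithelium cannot be told apart from a response to AAI: less the kidney-enriched mean, which no factor per array moves, the leukocyte list was -0.22 ± 0.12 and the stromal and endothelial lists 0.08 ± 0.06 and 0.08 ± 0.04 (-0.17 ± 0.29, 0.09 ± 0.15 and 0.10 ± 0.09 in the fixed block). An effect of AAI thus remains open, and miR-451-5p stayed lower unscaled (-2.36).

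miR-451-5p was -2.73 ± 0.34 at day 6. With slide as a fixed block it was -3.07 ± 0.78, and without AAI day 4 array 2 the call ended at -2.83 ± 0.88 with a wider error. Both values go against slide as the whole cause, but they rest on the few arrays that link the slides. miR-451-5p was also the largest fall on these same arrays, a choice the errors leave out. Within slide 1 it was -2.05 ± 0.35 from day 4 to day 6, a fall that a difference between slides cannot give. That slide holds no vehicle array, so this covers only the change between these days. Less blood in the sampled tissue and a response to AAI cannot be told apart, because the other red-cell miRNA, miR-144-3p, was detected on only 3 of 5 vehicle arrays. Its day 6 difference of -1.94 goes with less blood but rests on values under detection, since it was detected on 3, 2 and 0 of 5 arrays at day 2, 4 and 6, and miR-144-5p on 0 arrays of any group. A response to AAI may thus be a hypothesis only, with 3 vehicle arrays too few for this test of less blood in the sampled tissue.

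Chance alone can be excluded for the counts at day 2 (4, where 1 of 100 splits, the real one, reached it and the highest other gave 1), day 4 (9; highest other 1), day 6 (68; 16), day 6 against day 2 (29; 6) and the F test (47; 2). This does not exclude slide, because the real groups of the first 4 differed by 4, 4, 5 and 5 arrays in slide and the highest other splits by 2, 2, 3 and 1. With slide as a fixed block the counts were 0, 19, 90 and 95, and 0 in limma for each without AAI day 4 array 2. Chance cannot be excluded for day 6 against day 4 (2; highest other 115, with 11 of 100 splits reaching 2). Between day 4 and day 2 the real count was 0, which all 100 splits reach whatever the data (highest other 3), so nothing follows about chance. The split with 115 put AAI day 4 arrays 1 and 2 with AAI day 6 arrays 1, 3 and 4. That points to a structure of the samples. Along the first principal component, the axis of largest variance over the 20 arrays (37.4%), these arrays lay at 1.44, 12.2, 2.89, 6.65 and 5.66. The other AAI day 4 and day 6 arrays were all negative on it. The positive arrays came from both days and from slides 1 and 2, and the cause was not tested. For day 6 against day 4 the count within slide 1 was 3.

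Changes differed between days for 2 miRNAs from day 4 to day 6, miR-34a-5p (1.83) and miR-451-5p (-1.91), and for 29 from day 2 to day 6. Of these, the rule named miR-34a-5p (2.12), miR-6216 (1.28), miR-21-3p (1.12), miR-34c-5p (1.11), miR-21-5p (0.99), miR-451-5p (-2.67), miR-192-3p (-0.55), miR-203b-3p (-0.49), miR-146a-5p (-0.47) and miR-378b (-0.45). Leaving out single arrays moved the count of 2 between 1 (AAI day 4 arrays 1 and 3, AAI day 6 arrays 1 and 5) and 8 (AAI day 6 array 4), with 6 and 5 without AAI day 4 arrays 2 and 5. The call lost with these 4 arrays was that of miR-34a-5p (adjusted p 0.0529 to 0.0601). Leaving out single arrays moved the count of 29 between 6 (AAI day 2 array 5) and 34, with 15 without AAI day 2 array 1 or 2 and 19, 16 and 8 without AAI day 6 arrays 1, 3 and 5. Of these named miRNAs, miR-21-3p lost its call against day 2 without AAI day 2 array 1, 2, 3 or 5 or AAI day 6 array 1, 2 or 5 (0.0545 to 0.0806). miR-192-3p lost it without AAI day 2 array 1, 4 or 5 or AAI day 6 array 3 or 5 (0.0505 to 0.0721), and miR-203b-3p without AAI day 2 array 1, 4 or 5 or AAI day 6 array 1 or 5 (0.0505 to 0.0725). miR-6216 lost it without AAI day 2 array 5 (0.0505) or AAI day 6 array 1 (0.0619) or 3 (0.0584), and miR-34c-5p and miR-21-5p without AAI day 2 array 5 (both 0.0505) or AAI day 6 array 5 (both 0.0592).

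A single array lay far from the other 4 of its group in 9 of 160 tests, where chance gives about 8. The gap over the range was 0.746 for detected miRNAs on AAI day 4 array 2 and 0.838 for the 75th percentile signal on AAI day 6 array 2. It was 0.759 for miR-196c-5p on AAI day 2 array 4, 0.719 for miR-338-5p and 0.839 for miR-877 on vehicle array 4, and 0.837 for miR-877 on AAI day 4 array 2. It was 0.757 for miR-192-3p on AAI day 6 array 4, 0.890 for miR-378b on AAI day 4 array 5 and 0.725 for miR-203a-3p on AAI day 4 array 4.

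Among miRNAs outside the tests, 11 were detected on at least 3 arrays of an AAI group and on no vehicle array, among them miR-125b-2-3p and miR-129-5p (1, 4 and 3 of 5 arrays at day 2, 4 and 6), miR-200a-5p (1, 2 and 4) and miR-6324 (1, 3 and 4).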

How the results depend on the processing

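Spike-in scaling and the settings without AAI day 4 array 2 (with slide as a block, or together with vehicle array 5) were chosen after seeing the data; unless stated, the cause was not tested. miRNA counts at day 2 (4) were 0 with normexp, detection on all 20 arrays (fewer tested), fixed or random slide block, the fixed block without array 2 and within slide 2, 2 with quantile, mean log2, replicate block and series table, 9 unscaled and 7 with spike-ins. Day 4 (9) gave 0 with normexp and the fixed block without array 2, 14 unscaled, 4 with software totals, 5 with detection on all arrays, 19 and 3 with fixed and random block. Day 6 (68) gave 24 with normexp, 34 unscaled, 27 with the median, 23 with software totals and with spike-ins, and 0 with the fixed block without array 2. Day 4 against day 2 (0) gave 34 with the fixed block. Day 6 against day 4 (2) gave 1 with normexp, unscaled, each slide block and only 2 groups, and 6 without both arrays. Day 6 against day 2 (29) gave 6 with normexp, 16 with quantile and with the percentile over all miRNAs, 3 unscaled and with software totals, 5 with the median, 95 and 0 with the fixed block with and without array 2, 18 with the series table and with only 2 groups, and 2 with spike-ins. The F test (47) gave 8, 25, 29, 21, 17 and 13 with normexp, quantile, percentile over all, unscaled, median and software totals, 23 with the random block, 25 with the series table, 16 with spike-ins and 0 with the fixed block without array 2. List shifts ranged over 0 to 2 (day 2), 0 to 4 (day 4) and 0 to 5 (day 6; 1, 2, 3 and 5 in the settings that moved it). Correlations between days were 0.578 and 0.667 (day 2 and 4; normexp, series table), 0.507 (day 2 and 6; normexp) and 0.789 (day 4 and 6; without both arrays). Leaving out 1 array gave 2 to 5, 7 to 14 and 57 to 77 calls at day 2, 4 and 6, 0 to 0, 1 to 8 and 6 to 34 for day 4 against 2, 6 against 4 and 6 against 2, 31 to 71 for the F test, 0 to 1, 0 to 1 and 0 to 2 list shifts, and correlations of 0.712 to 0.816, 0.635 to 0.748 and 0.802 to 0.909. Reversed with normexp were miR-21-3p (-0.0309), miR-23a-5p (-0.11), miR-465-5p (-0.0120) and miR-551b-5p (-0.0044) at day 2, miR-489-3p (-0.0791) at day 4 and miR-338-5p (-0.0614) at day 6. Reversed unscaled, where the median rose, were miR-196c-5p (0.0156) and miR-361-5p (0.0746) at day 4 and let-7b (0.0678), let-7d (0.0189), miR-107-3p (0.0379), miR-196a-5p (0.0550), miR-196b-5p (0.0396), miR-214-3p (0.12; 0.00559 with spike-ins) and miR-30e-3p (0.0559) at day 6. The series table reversed miR-489-3p (-1.90, day 4) and miR-338-5p (-1.15, day 6). Software totals reversed miR-34c-5p (-0.94), miR-34b-5p (-0.90), miR-338-5p (-0.51), miR-877 (-0.0858), miR-203b-3p (0.0340) and miR-18a-5p (-1.85) at day 6 and, against day 2, miR-21-3p (-0.76), miR-34c-5p (-0.52), miR-34b-5p (-0.60) and miR-203b-3p (0.12). miR-18a-5p was -0.30 and -0.24 with the fixed block with and without array 2. With replicate number as a block, counts at day 4 and 6 were 8 and 65. Equal numbers did not pair arrays, with 11 of 30 same-number correlations above 0.1 (median -0.07) and 4 of 20 arrays closest to their own number. Of named day 6 values under other alternatives, 492 kept their call, 149 lost it and 18 reversed. Low signal over background limits miRNAs detected on few vehicle arrays.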

Other observations

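The miRNAs below were chosen after their values were seen. Outside the lists, both strands of the miR-140 locus, a regulator of cartilage and matrix genes, fell at day 6 (miR-140-5p -0.43 ± 0.10 and miR-140-3p -0.35 ± 0.09, n = 5 per group, limma adjusted p 0.00459 and 0.00503). miR-181b-5p (-0.44 ± 0.09) and miR-181a-5p (-0.24 ± 0.07) fell, while miR-181d-5p (-0.20 ± 0.10, adjusted p = 0.121) and miR-181c-5p (-0.04 ± 0.12, 0.818) did not pass. Of the pair from one transcript, miR-212-3p rose (0.65 ± 0.17, 0.00771) while miR-132-3p, detected on 2 of 5 vehicle arrays, was 0.72 ± 0.30 (0.0828). The lower ones fall among the 49 whose median was 0.0171 unscaled.

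Among miRNAs of other tissues, miR-133b-3p of muscle and miR-375-3p of pancreas were detected on all 5 arrays of each group. miR-122-5p of liver was detected on 1, 0, 2 and 1 of 5 arrays in vehicle and at day 2, 4 and 6, and the muscle miRNA miR-1-3p on 0 arrays of any group.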
